A study of Drosophila melanogaster with 21 samples.

How the data were processed

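RNA was measured in 21 libraries from Drosophila melanogaster, in 9 groups. Schneider S2 cells, a line derived from fly embryos, gave 6 libraries (3 groups of 2). Adult female brains gave 6 libraries (3 groups of 2) and ovaries 9 (3 groups of 3). Per the labels' protocols, the S2 libraries were made with a kit that reads the 3' end of polyadenylated RNA and were sequenced to 75 bp. The brain and ovary libraries were made from RNA depleted of ribosomal RNA with a kit that keeps the strand. The design text states single reads and calls the replicates biological. It does not say whether replicates were separate cultures or dissections, so p-values measure the spread between these samples.

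The S2 table holds whole-number counts per transcript, which the authors deposited without normalization. The aligner and counter of that table are not given in the sources used here. The brain and ovary tables hold estimated counts per gene, deposited by the authors, of which 9.73% (brain) and 7.31% (ovary) of the values were not whole. The submitters' processing notes name the genome build dm3 for these samples, and Trim Galore 0.6.2 and Salmon 1.2.1 for the tissue samples. Whether counting used the strand is not given in the sources used here, so values of overlapping and antisense genes are uncertain. Reads shared between near-identical copies, such as those of some ribosomal protein and glutathione transferase genes, could have been split by the counting, and values of such genes are uncertain too. The annotation used here was of build BDGP6, and it served for gene names, chromosome arms and the position of CG11247. No coordinates of dm3 were used.

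Of 26009 transcripts in the S2 table, 25653 matched a gene of this annotation. The other 356 carried 0.361% to 0.418% of the counts of a library and stayed out of the gene tests. Of the 11010 genes, 5897 had 2 or more isoforms, and in 4042 of these at least 1 pair of isoforms had identical counts in every library. Reads at a shared 3' end therefore appeared in the table more than once. Each S2 gene was represented by its isoform with the highest total, and the sum of isoforms was run as an alternative. In the tissue tables of 13955 genes, 272 identifiers were matched through their symbol, 59 that matched ambiguously were kept as in the file, and 22 stayed unmatched. Estimated counts were rounded to whole numbers. No value column lacked a sample.

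Total counts over genes were 6.4 to 9.1 M in S2 libraries, 39.0 to 45.6 M in brain and 14.1 to 21.5 M in ovary. The S2 table itself sums to 18.4 to 26.7 M, because isoforms repeat reads. Log-scale correlations between replicates were 0.959 to 0.975 in S2 cells, 0.991 to 0.992 in brain and 0.981 to 0.994 in ovary. Counts of replicate pairs differed by far more than sampling noise (chi-square per degree of freedom 5.45 to 50.1), so no library was counted as a duplicate.

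Groups were compared with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test, with TMM scaling, the edgeR low-count filter and robust dispersion estimates. All groups of a system entered 1 fit without a replicate term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. After filtering, 7152 genes were tested in S2 cells, 9880 in brain and 8312 in ovary. The brain-minus-ovary contrast was fitted on all tissue libraries over 10029 genes. The counts per M (CPM) printed here are TMM-scaled, and means carry the SD over libraries. Log2 fold changes carry an SE computed as the absolute change divided by the square root of the F statistic. This SE can be unreliable for genes near 0 counts. Where control libraries held 0 counts, the fold is a lower bound against 3 counts over the group. Where they held 1 to 3 counts, the ratio has a 95% exact counting interval. These bounds and ratios use counts summed over a group, divided by its summed TMM-scaled library sizes, so they differ from ratios of mean CPM. Such bounds and intervals cover counting error only.

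The design, the tests, the gene lists and the rule for named genes were fixed before the data were examined, except where a choice is said to follow the data. In S2 cells the rule named the 10 genes higher and 10 lower with the largest changes among called genes with a mean CPM of at least 5 and no overlap between groups. In brain and ovary it named 10 per direction among genes called in both mutants, ranked by the smaller of both changes. Direct contrasts gave up to 3 per direction, gene lists up to 4 called members per contrast, and genes shared between systems up to 10. CG11247 was always named. Lists with at least 5 tested members were tested with limma 3.58.1 camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The lists were chromatin genes (H3K9 methylation with HP1 and corepressors, Polycomb group, insulator proteins), developmental transcription factors, neuronal genes, neuropeptides, glia, clock, photoreceptor, fat body, muscle, hemocyte, gut and spermatheca markers, chorion and vitelline membrane genes, female germline genes, piRNA pathway genes, testis genes, transposable elements, immune genes, heat shock genes, xenobiotic genes, ecdysone response genes, cell cycle genes, ribosomal protein genes and oxidative phosphorylation genes. None of the 128 transposable element names matched an entry, so transposable elements were not analysed here.

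Whether replicate numbers pair the libraries was checked from deviations from the group means. In S2 cells libraries with the same number deviated together (correlations 0.62, 0.72 and 0.59 between groups), and the first principal component, with 57.0% of the variance, separated the numbers. S2 results from a fit with the replicate number as a block are therefore given where they change a call or a count. This pairing comes from the data and not from the labels.

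On simulated counts with 200 changed genes, the test recovered 15% of 2-fold and 85% of 4-fold changes for S2 cells at 24 h, and 20% and 83% at 48 h, over 7044 genes. For brain it recovered 81% and 94% (mutant 1) and 83% and 96% (mutant 2) over 9809 genes. For ovary the values were 92% and 98% (mutant 1) and 88% and 98% (mutant 2) over 8221 genes. Unchanged genes made up 9.09% and 10.4% of the simulated S2 calls, 8.85% and 6.77% of the brain calls, and 5.0% and 5.58% of the ovary calls. In S2 cells the share was higher with the replicate block (13.2% at 24 h and 15.04% at 48 h) and with DESeq2 over 7152 genes (15.9% and 14.7%). With DESeq2 it was 9.28% and 11.4% in brain over 9880 genes, and 11.1% and 9.52% in ovary over 8312. The simulated counts held no replicate effect, and their spread came from fits without the block. The shares with the block may therefore not hold for the real S2 libraries.

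The chance overlap of comparisons that share controls was taken from 100 simulated tables of unchanged groups. Overlaps between systems were tested with two-sided Fisher's exact tests. Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, the replicate block and leaving out each library in turn. After the data were seen, 3 more were added: summed isoforms, ovary fits without 3 libraries that stand apart, and S2 calls from the blocked fit in the overlaps.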

Results

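The series followed CG11247 (Saft), a zinc-finger transcription factor, by removing it in a cell line and in flies. In S2 cells the endogenous gene carries a degron tag on both copies, so that the plant hormone auxin leads to degradation of the protein. Cells received 500 µM auxin for 24 h or 48 h, or solvent only, with 2 libraries per group. No auxin-treated cells without the tag were among the samples. In flies, a 1 bp deletion in exon 1 (mutant 1) and a 2 bp deletion in exon 2 (mutant 2) were made in the same isogenised parent strain, which served as wild type. Each brain library pooled 40 brains (n = 2 per genotype) and each ovary library 5 ovary pairs (n = 3 per genotype) of mated females 3 to 4 days old. The labels list both mutant stocks over a third-chromosome balancer, and whether dissected females were homozygous is not stated in the sources used here. Depth was 6.4 to 9.1 M counts over genes in S2 cells, 39.0 to 45.6 M in brain and 14.1 to 21.5 M in ovary.

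CG11247 (FBgn0037120) lies on chromosome arm 3L at 21724326 to 21728806 on the minus strand in build BDGP6. Its mRNA level cannot check the depletion in S2 cells, because the degron acts on the protein, and a frame shift need not lower an mRNA. In S2 cells the level was 19.8 ± 2.14 CPM (SD, n = 2) untreated, 25.5 ± 3.20 at 24 h and 26.8 ± 2.51 at 48 h, and neither difference passed the test (edgeR adjusted p = 1.00 for both). In brain it was 87.8 ± 2.68 CPM in wild type, 65.9 ± 0.713 in mutant 1 (log2 -0.41 ± 0.06, edgeR adjusted p = 0.0039) and 107 ± 4.5 in mutant 2 (0.28 ± 0.05, adjusted p = 0.030). In ovary it was 62.8 ± 4.08 CPM in wild type and 30.1 ± 0.733 in mutant 1 (-1.06 ± 0.06, edgeR adjusted p = 1.3e-07). Ovaries of mutant 2 had 72.6 ± 2.27 CPM (0.21 ± 0.06, edgeR adjusted p = 0.035). The brain call of mutant 1 was lost without wild-type library 2 or mutant 1 library 1 (edgeR adjusted p = 0.0511 each), and that of mutant 2 without wild-type library 1 (0.284) or 2 (0.13). The ovary call of mutant 2 was lost without wild-type library 1 (edgeR adjusted p = 0.107) or 2 (0.14), or without mutant 2 library 1 (0.0535), 2 (0.0964) or 3 (0.0954), and without the 3 libraries that stand apart in ovary (0.199).

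Depletion in S2 cells was asked which genes respond to loss of the protein within 24 h and 48 h. At both times a small set of genes rose, most of them from under 5 CPM. snu (FBgn0039594), an ABC transporter of the cuticle lipid barrier, rose from 0.346 ± 0.0584 CPM to 39.5 ± 8.40 at 24 h (log2 6.76 ± 0.39, edgeR adjusted p = 0.0029) and 53.9 ± 12.4 at 48 h (7.21 ± 0.39, 0.0018). rtv (FBgn0261277), required for chitin organisation, rose from 0.737 ± 0.678 to 51.9 ± 1.87 and 49.9 ± 5.97 CPM (6.17 ± 0.45 and 6.11 ± 0.45, edgeR adjusted p = 0.0048 and 0.0051). qsm (FBgn0028622), which encodes a zona pellucida domain protein, rose from 3.16 ± 0.816 to 57.6 ± 9.85 and 70.8 ± 14.2 CPM (4.17 ± 0.29 and 4.47 ± 0.30, edgeR adjusted p = 0.0048 and 0.0039). Cad96Ca (FBgn0022800), a receptor tyrosine kinase gene, had 0 counts in untreated cells and was at least 30.7-fold higher at 24 h and at least 42.6-fold higher at 48 h (edgeR adjusted p = 0.0370 and 0.0236). Rcd6, conv (4.26 CPM untreated) and CG9782 (55.7 CPM untreated) rose at both times, by 3.74 ± 0.35, 2.70 ± 0.26 and 1.56 ± 0.16 at 24 h and by 3.80 ± 0.35, 2.85 ± 0.26 and 1.73 ± 0.16 at 48 h on the log2 scale (edgeR adjusted p at most 0.0267). Dlish (FBgn0034264), a Fat pathway gene, was called at 48 h, with 6.51 ± 0.582 CPM against 0.141 ± 0.0164 (ratio of summed counts 46.3, counting interval 12.5 to 387, edgeR adjusted p = 0.0275). These genes were all those called: 7 of 7152 at 24 h and 8 at 48 h, all higher in both treated libraries than in both untreated ones. At an unadjusted p under 0.05, edgeR gave 80 higher and 63 lower genes at 24 h and 91 and 61 at 48 h. These totals were under a share of 0.05 of the 7152 genes, which unchanged genes alone would give on average. DESeq2 called 15 higher and 0 lower genes at 24 h, and 17 higher and 1 lower at 48 h.

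With the replicate number as a block, 75 genes were higher and 63 lower at 24 h, and 110 and 81 at 48 h, and these included all 7 and all 8 of the genes above. On simulated counts, unchanged genes made up 13.2% and 15.04% of the calls of this fit. Those counts held no replicate effect and took their spread from the fit without the block. The shares may therefore not hold for the calls on the real libraries. lft, Tep3 and Hil, named because they changed in both tissues, were called at 24 h with the block (edgeR adjusted p at most 2.8e-12; 0.0722, 0.116 and 0.309 without it) and at 48 h (at most 2.5e-12; 0.0952, 0.0578 and 0.256 without it). Without the block, all 3 were also called by DESeq2 (adjusted p at most 0.00895 at 24 h and 0.00362 at 48 h) and by edgeR without a low-count filter (at most 0.00118 and 4.3e-04). Tep3 at 48 h was called too with RLE size factors (edgeR adjusted p = 0.0495) or without untreated library 2 (0.0407). Dlish at 24 h (edgeR adjusted p = 4.1e-09 with the block, 0.0521 without) and CBP at both times (0.0289 and 0.00926 with the block, 1.00 without) were called in the fit with the block and not in that without it. Without a low-count filter 26 genes were called at 24 h and 36 at 48 h. Fits with a library left out had no replicate block, so the pairing of the S2 libraries stayed in their spread. Whether calls lost in them would hold with the block was not tested. Leaving out library 1 of 24 h auxin left 1 call there, leaving out untreated library 2 or 24 h library 2 left 3, and without untreated library 1 there were 4. At 48 h, 5 genes were called without untreated library 1 and 4 without 48 h library 1. CG9782 was lost at 24 h without any single library (edgeR adjusted p 0.148 to 0.319) and with isoforms summed (0.0693). Cad96Ca was lost at 24 h without untreated library 1 (edgeR adjusted p = 0.144) or 2 (0.0617) or 24 h library 1 (0.319) or 2 (0.216), and with isoforms summed (0.0806). At 48 h it was lost without untreated library 1 (edgeR adjusted p = 0.0846) or 48 h library 1 (0.0894) or 2 (0.0516), and with isoforms summed (0.0629). Dlish at 48 h was lost without untreated library 1 (edgeR adjusted p = 0.298) or 2 (0.159) or 48 h library 1 (0.0932) or 2 (0.123), and with isoforms summed (0.0746). At 24 h rtv and qsm were lost only without 24 h library 1 (0.0521 each). conv was lost at 24 h without any single library (edgeR adjusted p 0.0555 to 0.224), and Rcd6 without untreated library 2 (0.0585), 24 h library 1 (0.224) or 24 h library 2 (0.124). At 48 h the call of conv was lost without 48 h library 1 (edgeR adjusted p = 0.0656), and that of CG9782 without untreated library 1 (0.141) or 2 (0.0745) or 48 h library 1 (0.0856). Called at both times were 7 genes, against 0.00783 for independent lists and at most 2 in simulated unchanged groups with the same controls. Fold changes at both times correlated across genes at 0.817 (0.506 in the simulation), with a covariance of 0.168 (0.121 simulated), and 76.0% had the same sign (66.8% simulated). These fits and the simulation left out the pairing by replicate number. Part of the excess may come from the shared untreated libraries. The direct comparison of 48 h with 24 h gave 0 calls with edgeR, with or without the block, and 0 with DESeq2. At an unadjusted p under 0.05 it gave 10 higher and 7 lower genes without the block, under a share of 0.05 of the tested genes.

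Of the gene lists in S2 cells, oxidative phosphorylation genes were higher as a group at 24 h (camera adjusted p = 0.0014, 56 of 66 members with a positive change, median log2 0.09) and at 48 h (0.0025, 54 of 66, median 0.09). Ribosomal protein genes were lower as a group at 24 h (camera adjusted p = 0.0378, 15 of 83 positive, median -0.08) and at 48 h (4.2e-07, 2 of 83 positive, median -0.17). No member of either list was called, over all genes or adjusted over the list alone. With an estimated correlation the adjusted p was 0.709 for both lists at 24 h and 0.663 for both at 48 h, and no list was called. The ribosomal call at 24 h was lost without 24 h library 2 (camera adjusted p = 0.994) or untreated library 1 (0.813, turned in direction), and at 48 h without untreated library 1 (0.336). The oxidative phosphorylation call at 24 h was lost without untreated library 2 (camera adjusted p = 0.0527) or 24 h library 2 (0.228), and at 48 h without untreated library 2 (0.118) or 48 h library 2 (0.406). With the block, camera also called heat shock genes lower (adjusted p = 0.0196 and 0.0220), xenobiotic genes higher (0.0109 and 0.0107) and, at 24 h, hemocyte markers lower (0.0109). With the block and an estimated correlation the adjusted p of these was 0.524 at 24 h and 0.612 at 48 h. Without the block, heat shock genes were called lower without untreated library 1 at 24 h (camera adjusted p = 1.2e-04) and 48 h (3.1e-04) and without 24 h library 2 (3.8e-04), but higher without untreated library 2 (0.0141 and 0.00836) or 24 h library 1 (0.00911). Leaving out 24 h library 1 also brought calls of hemocyte markers (camera adjusted p = 0.0393) and xenobiotic genes (0.043). Leaving out 48 h library 1 did the same (0.0358 and 0.00968), and without 48 h library 2 immune genes were called (0.0373). The other 18 lists gave camera adjusted p values of 0.098 to 0.897 at 24 h and 0.0875 to 0.91 at 48 h without the block, with 0 members called. Adjusted over the list alone, 1 xenobiotic gene was higher at 48 h.

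In brain, both mutant strains were compared with the parent strain. The genes that rose most did so from near 0 in both. Cpr62Bc, a cuticle protein gene, went from 0.0343 ± 0.0158 CPM in wild type to 24.9 ± 3.23 in mutant 1 and 25.4 ± 1.89 in mutant 2 (ratios of summed counts 721, counting interval 246 to 3500.3, and 739, 252 to 3585, edgeR adjusted p = 3.8e-08 and 4.1e-08). reb and exp, a neighbouring gene pair needed for chitin deposition, rose by 6.37 ± 0.18 and 6.22 ± 0.16 on the log2 scale in mutant 1, and by 6.41 ± 0.18 and 6.29 ± 0.16 in mutant 2 (edgeR adjusted p at most 7.6e-08). CG8172 had 0 counts in wild type and was at least 643-fold higher in mutant 1 and at least 708-fold higher in mutant 2, with 22.2 ± 3.40 and 24.6 ± 4.94 CPM (edgeR adjusted p = 4.8e-04 and 4.2e-04). CG7432 (23.5 and 23.9 CPM in mutants 1 and 2), CG8192 (36.7 and 38.9), CG12607 (10.2 and 9.11), cysu (9.09 and 9.37), CG6026 (43.6 and 43.7) and CG13643 (21.6 and 22.9) had at most 0.264 CPM in wild type (edgeR adjusted p at most 1.7e-06 in both). Mutant 1 had 188 genes higher and 75 lower of 9880, and mutant 2 had 220 and 72. Of these, 123 and 126 were higher by at least 2-fold, and 18 and 19 lower by as much.

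The genes that fell most in brain included markers of hemocytes, the blood cells of flies. Obsc, which encodes the muscle protein obscurin, was lower in mutants 1 and 2 (log2 -1.46 ± 0.11 and -1.57 ± 0.11, edgeR adjusted p = 4.5e-04 and 2.8e-04). Tep1, a thioester protein gene, was lower too (-1.29 ± 0.12 and -1.36 ± 0.13, edgeR adjusted p = 4.8e-04 and 3.3e-04). The phagocytosis receptor genes NimC2 and eater went from 21.6 and 19.9 CPM to 10.0 and 11.2 in mutant 1 (log2 -1.11 ± 0.14 and -0.83 ± 0.12), and to 10.1 and 9.12 in mutant 2 (edgeR adjusted p at most 0.0054). The laminin genes LanA and LanB2 were lower in mutant 1 (-0.79 ± 0.06 and -0.78 ± 0.06) and in mutant 2 (-0.95 ± 0.06 and -0.90 ± 0.06, edgeR adjusted p at most 1.1e-04). GstD3, Had2, CG15695 and CG4950 also fell in both mutants (log2 -0.69 to -1.27, edgeR adjusted p at most 0.0186). Calls of mutant 1 were lost for eater without mutant 1 library 2 (edgeR adjusted p = 0.0508) and for Had2 without wild-type library 1 (0.105) or mutant 1 library 1 (0.102) or 2 (0.107). In the same comparison CG4950 was lost without wild-type library 1 (edgeR adjusted p = 0.0566) or mutant 1 library 1 (0.066) or 2 (0.0868). CG15695 was lost in both mutants without wild-type library 1 (edgeR adjusted p = 0.12 and 0.108) or 2 (0.111 and 0.1), and in mutant 1 without its library 2 (0.164).

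Called in both brain mutants with the same sign were 172 higher and 51 lower genes. Independent lists of these sizes would share 4.19 and 0.547 genes, and simulated unchanged groups against the same controls shared at most 2 and 3. Fold changes of both mutants correlated across genes, which are not independent replicates, at 0.848 (0.491 in the simulation), with a covariance of 0.332 (0.0634 simulated), and 74.9% had the same sign (66.6% simulated). With 2 wild-type libraries the controls could not be split, so part of the excess may come from sharing them. Compared directly, mutant 2 differed from mutant 1 in 4 genes. These were CG11247 (0.69 ± 0.06, edgeR adjusted p = 0.0074), CBP, a calcium-binding protein gene, which was lower in mutant 2 than in mutant 1 (-0.94 ± 0.09, 0.0214), and, named after their values were seen, CG13875 (-2.05 ± 0.24, 0.0475) and CG14861 (0.0475). Against wild type, the mean log2 change of CBP over both brain mutants was 3.48. CG14861 had 0 counts in wild-type and mutant 1 libraries and 1.38 and 1.07 CPM in those of mutant 2. DESeq2 called 15 genes there. Leaving out mutant 1 library 1 left 0, and CG11247 (edgeR adjusted p = 0.108) and CBP (0.131) lost their calls. There were 12 without mutant 1 library 2, where CBP was lost (0.105), and 80 without mutant 2 library 1. At an unadjusted p under 0.05, 140 genes were higher and 101 lower in mutant 2 than in mutant 1, under a share of 0.05 of the tested genes. Counts of calls moved with single libraries: mutant 1 had 172 calls without wild-type library 2 and 149 without its own library 1. Mutant 2 had 167 without wild-type library 2 and 539 without its own library 1, and 142 genes were called in both without mutant 1 library 1. The mean of both mutants had 223 genes higher and 102 lower, with 201 in all without wild-type library 2 and 536 without mutant 2 library 1 or 2.

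Hemocyte markers were lower in mutant brains as a group: of 21 tested, 12 fell and 0 rose (18 lower adjusted over the list alone), with a median log2 change of -0.59 in the mean of both mutants (camera adjusted p = 2.8e-23). LanB1 (-0.59 ± 0.05) and NimC1 (-0.63 ± 0.06) were among them. With an estimated correlation the adjusted p was 0.803, and fry gave 0.0712. Fat body markers were lower too (camera adjusted p = 3.3e-05, median -0.34, adjusted p = 0.803 with an estimated correlation), with 3 of 18 lower and 1 higher (6 and 2 adjusted over the list alone). Fbp1 (-2.22 ± 0.18), Lsp1gamma (-2.39 ± 0.22) and Obp44a (-0.69 ± 0.10) fell, while Desat1 rose by 0.34 ± 0.07. Ribosomal protein genes were higher, with 81 of 82 positive, 7 called (41 adjusted over the list alone) and a median of 0.20 (camera adjusted p = 2.0e-25, adjusted p = 0.803 with an estimated correlation), RpL38 by 0.34 ± 0.05. In mutant 1 alone 0 ribosomal members were called by edgeR (0 adjusted over the list alone, median 0.13), and in mutant 2 alone 13 (68 adjusted over the list alone, median 0.26). Immune genes had a median of 1.60 with 35 of 40 positive (camera adjusted p = 6.8e-06, adjusted p = 0.848 with an estimated correlation), but only BomT1 rose (2.90 ± 0.53) and Tep1 fell (2 higher and 1 lower adjusted over the list alone).

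Xenobiotic genes in brain were lower as a group (camera adjusted p = 0.0264, median -0.10, adjusted p = 0.900 with an estimated correlation), with 3 of 48 higher and 5 lower (3 and 8 adjusted over the list alone). Cyp6g1 and Cyp6g2 rose by 1.79 ± 0.16 and 0.77 ± 0.11, and GstD3 (-0.83 ± 0.08) and Jheh2 (-0.28 ± 0.05) fell. piRNA pathway genes were lower (camera adjusted p = 0.0224, median -0.13, adjusted p = 0.803 with an estimated correlation) with 0 of 24 called. In mutant 1 alone both lists were called (camera adjusted p = 0.0140 and 0.00528, adjusted p = 0.823 for each with an estimated correlation), and in mutant 2 alone neither (0.0954 and 0.137). In mutant 2 alone oxidative phosphorylation genes (camera adjusted p = 0.0140, adjusted p = 0.780 with an estimated correlation) and neuropeptide genes (0.0379, 23 of 33 positive, adjusted p = 0.708 with an estimated correlation) were called higher, with 0 members called, and in mutant 1 alone neither (0.263 and 0.668). The xenobiotic call was lost without wild-type library 1 (camera adjusted p = 0.137), mutant 1 library 1 (0.0841) or 2 (0.083), or mutant 2 library 1 (0.428), and the piRNA call without wild-type library 1 (0.117) or mutant 2 library 2 (0.0918). Heat shock genes, uncalled (camera adjusted p = 0.231, 0 of 21 called), became lower without wild-type library 1 (2.45e-10), mutant 1 library 2 (0.0147) or mutant 2 library 1 (0.0371). Photoreceptor markers (0.300, ninaB lower by -0.24 ± 0.04) became lower without wild-type library 2 (camera adjusted p = 4.2e-06) or mutant 1 library 1 (5.8e-04). Without single libraries camera also called gut markers (0.0253 without wild-type library 1, 1.3e-04 without mutant 1 library 1), muscle markers (0.0231 without mutant 1 library 1, 0.0215 without mutant 2 library 2) and oxidative phosphorylation genes (3.6e-04 without mutant 2 library 1). Without mutant 2 library 2 it called glia markers (0.0301) and female germline genes (0.00215). Neuronal genes had 0 of 54 members called (camera adjusted p = 0.300, 2.4e-06 without mutant 2 library 2), while ImpE1 (2.17 ± 0.05) and Ldh (0.57 ± 0.12) rose among 28 ecdysone response genes (0.576). Single called members of other uncalled lists were ovo (0.94 ± 0.09), slp1 (0.48 ± 0.09), nrv2 (-0.26 ± 0.05) and Ilp5 (-0.23 ± 0.04), and Obsc, Zasp52 (-0.49 ± 0.07) and Act79B (-0.66 ± 0.12) fell among 24 muscle markers. Gut, spermatheca, chorion, testis, clock, cell cycle, oxidative phosphorylation, H3K9, Polycomb and insulator lists had 0 called members in brain (camera adjusted p 0.224 to 0.973).

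In ovary the same comparison gave the largest number of calls of the 3 systems. spz4, a gene of the Spätzle family of secreted ligands, had 0 counts in wild type and 106 ± 5.32 and 103 ± 6.17 CPM in mutants 1 and 2, at least 1648-fold and 1583-fold higher (edgeR adjusted p = 1.5e-11 and 1.7e-11). kkv, the chitin synthase of the cuticle, rose from 0.866 ± 0.593 CPM to 657 ± 13.1 and 661 ± 21.9 (log2 9.50 ± 0.19 and 9.51 ± 0.19, edgeR adjusted p = 2.6e-11 and 2.5e-11). uif, which encodes a transmembrane protein of tracheae, rose from 1.09 ± 0.415 to 718 ± 73 and 776 ± 47.5 CPM (9.34 ± 0.16 and 9.46 ± 0.16, edgeR adjusted p = 1.9e-12 and 1.8e-12). sha, needed for epidermal hairs, rose from 0.0706 ± 0.0690 to 254 ± 12.1 and 251 ± 9.16 CPM (ratio of summed counts 3933 in mutant 1, counting interval 1345 to 19072, edgeR adjusted p = 2.7e-13). With 0 counts in wild type, dyl was at least 538-fold higher in mutant 1 and 646-fold in mutant 2, NT1 368- and 392-fold, slf 183- and 213-fold, and CG11905 123- and 136-fold. Sb, the serine protease gene Stubble, and CG6118 rose from 0.0459 and 0.0181 CPM to 25.2 and 17.3 in mutant 1, and to 24.3 and 19.1 in mutant 2 (ratios of summed counts in mutant 1 593, counting interval 164 to 4900.0, and 796, 143 to 31492, edgeR adjusted p at most 4.4e-09). The labels give the balancer of the mutant stocks a dominant Sb marker.

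Among genes that fell in ovary, bnb went from 14.3 CPM to 1.09 and 1.25 in mutants 1 and 2 (log2 -3.71 ± 0.26 and -3.50 ± 0.25) and CG9380 from 12.5 to 1.04 and 2.11 (edgeR adjusted p at most 2.9e-06). CG4066 (-2.28 ± 0.17 and -2.18 ± 0.16), RhoGAP100F (-1.90 ± 0.16 and -2.12 ± 0.16) and Mco1, a multicopper oxidase gene (-1.73 ± 0.14 and -2.29 ± 0.14), fell. CG16956, tty, Dhc98D, CG8745 and CG10175 fell too (log2 -1.35 to -2.17, edgeR adjusted p at most 0.00897). The call of Dhc98D in mutant 1 was lost without mutant 1 library 3 (edgeR adjusted p = 0.0587). Mutant 1 had 1018 genes higher and 935 lower of 8312, and mutant 2 had 729 and 611. Most changes were small: 280 and 295 genes were higher by at least 2-fold, and 84 and 64 lower. On the second principal component (11.9% of the variance) wild-type library 2, mutant 1 library 1 and mutant 2 library 3 stood apart. Without these 3 libraries, an alternative added after the data were seen, mutant 1 had 912 higher and 821 lower genes and mutant 2 had 398 and 216. Mutant 1 had 1163 calls without wild-type library 1, 996 without wild-type library 2 and 1038 without its own library 3. Mutant 2 had 673 without wild-type library 1, 624 without wild-type library 2, and 882, 604 and 736 without its own libraries 1, 2 and 3.

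Called in both ovary mutants with the same sign were 615 higher and 528 lower genes, against 89.3 and 68.7 for independent lists and at most 1 and 1 in simulated unchanged groups. Without the 3 libraries that stand apart there were 338 and 189, of which 497 in all were shared with the first set, so the share of higher genes moved from 53.8% to 64.1%. Fold changes of both mutants correlated across genes at 0.960 (0.525 in the simulation), with a covariance of 0.861 (0.0701 simulated), and 88.4% had the same sign (67.1% simulated). Splitting 3 wild-type libraries leaves fewer than 2 in a part, so part of the excess may come from the shared controls. In each tissue 1 gene was called in both mutants with opposite signs, and in each it was CG11247. In the direct comparison of the mutants 1 gene differed, CG11247 (1.27 ± 0.06 higher in mutant 2, edgeR adjusted p = 7.9e-07). There 189 higher and 126 lower genes had an unadjusted p under 0.05, which is under a share of 0.05 of the tested genes. DESeq2 called 11 in this comparison, and 18 were called without the 3 libraries that stand apart, with 4 without mutant 1 library 1 and 6 without mutant 2 library 3. Genes called in both numbered 594 without wild-type library 1, 527 without wild-type library 2, 567 without mutant 2 library 2 and 653 without mutant 2 library 3. The mean of both mutants had 1214 genes higher and 1165 lower, with 1437 in all without wild-type library 1 and 1140 without library 2.

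**Figure D1:**
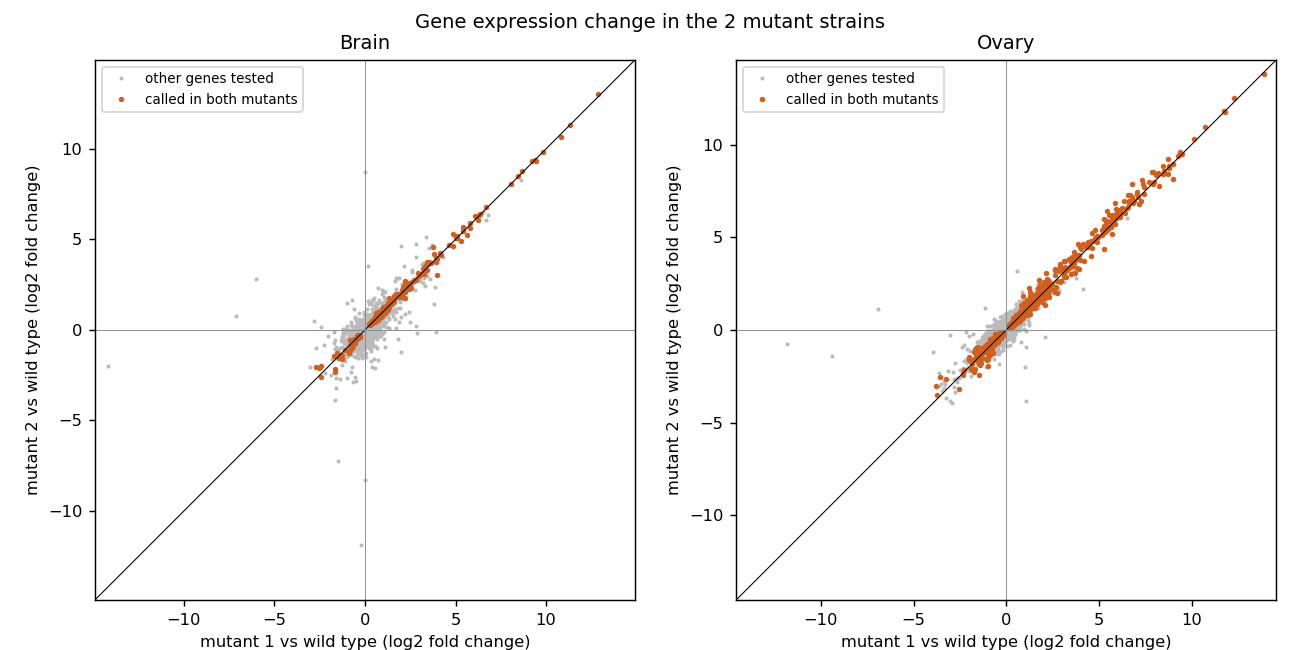
Log2 fold change against wild type in mutant 1 (horizontal axis) and mutant 2 (vertical axis) for each tested gene, in brain and in ovary. Orange points are genes called in both mutants with the same sign (172 higher and 51 lower in brain, 615 and 528 in ovary), and the line marks equal change.

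Chorion and vitelline membrane genes were lower in mutant ovaries: 14 of 24 fell and 0 rose (16 lower adjusted over the list alone), with a median log2 change of -0.53 in the mean of both mutants (camera adjusted p = 3.2e-10). ndl (-0.75 ± 0.05), Vm26Ac (-1.11 ± 0.08), fs(1)N (-0.46 ± 0.04) and Cp19 (-1.26 ± 0.12) fell. With an estimated correlation the adjusted p was 0.102, and fry gave 3.0e-04. Oxidative phosphorylation genes (30 of 67 lower, 34 adjusted over the list alone, median -0.19, camera adjusted p = 4.3e-08) and ribosomal protein genes (29 of 84 lower, 36 adjusted over the list alone, median -0.16, 5.0e-07) were lower (adjusted p = 0.647 for each with an estimated correlation). Cyt-c1 (-0.35 ± 0.06) and RpS5a (-0.46 ± 0.08) fell. Cell cycle genes were higher, with 17 of 58 up and 1 down (18 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.0015, adjusted p = 0.647 with an estimated correlation), such as glu (0.36 ± 0.05) and Klp61F (0.32 ± 0.05). Muscle markers were higher, with 10 of 22 up (13 adjusted over the list alone, median 0.41, camera adjusted p = 0.0013, adjusted p = 0.647 with an estimated correlation), up and wupA by 0.68 ± 0.16 and 0.55 ± 0.14. In mutant 1 alone 2 muscle markers were up (median 0.22) and the list was not called (camera adjusted p = 0.0607), and in mutant 2 alone 10 were up (median 0.51, 9.0e-06, adjusted p = 0.703 with an estimated correlation). Immune genes were higher, with 8 of 21 up (9 adjusted over the list alone, median 0.27, camera adjusted p = 0.0030, adjusted p = 0.647 with an estimated correlation), Tep2 by 1.90 ± 0.09 and PGRP-LC, a receptor of the Imd pathway, by 1.51 ± 0.19. Genes of H3K9 methylation, HP1 and corepressors were higher by small amounts (7 of 25 up, 7 adjusted over the list alone, median 0.07, camera adjusted p = 0.0149). So were Polycomb group genes (3 of 22 up, 0 adjusted over the list alone, median 0.11, camera adjusted p = 0.0127). With an estimated correlation the adjusted p was 0.647 for each of these lists. The corepressor gene Sin3A rose by 0.23 ± 0.06. Both camera calls held in mutant 1 alone (camera adjusted p = 0.00776 and 0.00577, adjusted p = 0.633 for each with an estimated correlation), and in mutant 2 alone neither list was called (0.0843 for both, 1 of 25 and 0 of 22 up). fry did not call muscle markers (adjusted p = 0.0847), ribosomal protein genes (0.137) or oxidative phosphorylation genes (0.0721). Without the 3 libraries that stand apart camera still called all 8 lists, with 11 chorion, 22 oxidative phosphorylation and 18 ribosomal protein genes lower, and 8 cell cycle genes and 1 Polycomb group gene higher.

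The other 15 lists tested in ovary were not called in the mean of both mutants. Of these, 14 held changed members. ple and Ddc, the enzymes of dopamine synthesis, rose by 6.19 ± 0.25 and 2.67 ± 0.28 among 23 neuronal genes (5 up, 1 down, camera adjusted p = 0.227). Among 26 ecdysone response genes 8 rose and 5 fell (0.422), with ImpE1 up by 4.20 ± 0.37, Blimp-1 by 3.64 ± 0.17 and ImpL2 by 1.00 ± 0.07, and Cyp18a1, which degrades ecdysone, lower by -1.07 ± 0.11. Fat body markers were called lower in mutant 1 alone (camera adjusted p = 0.0495, adjusted p = 0.633 with an estimated correlation) and not in mutant 2 (0.134). In the mean of both mutants 3 of 13 were lower and 1 higher (0.0701), with the yolk protein genes Yp1 and Yp2 lower by -0.68 ± 0.09 and -0.58 ± 0.08, and the list was called lower without wild-type library 3 (camera adjusted p = 7.0e-04) or mutant 2 library 1 (0.0445). Hemocyte markers had 4 up and 4 down of 19 (0.743), PPO1 and PPO2 up by 1.39 ± 0.25 and 1.21 ± 0.23. Insulator genes had 5 of 17 up (camera adjusted p = 0.134), CTCF by 0.33 ± 0.06, and fry called them (adjusted p = 0.0146) and the ecdysone response genes (0.021). Among piRNA pathway genes 3 rose and 6 fell of 30 (0.554), and among female germline genes 3 rose and 2 fell of 30 (0.958). Xenobiotic genes had 6 up and 5 down of 41 (0.754), and heat shock genes 3 up and 5 down of 19 (0.666). Glia markers had 1 up and 4 down of 12 (0.374), clock genes 1 up and 2 down of 11 (0.608), neuropeptides 2 down of 5 (0.374), testis genes 1 up and 1 down of 10 (0.534), developmental transcription factors 3 up and 1 down of 14 (0.754), with kni up by 3.86 ± 0.51, and photoreceptor markers 0 of 8 (0.958).

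Genes that rose were shared between the systems. Of genes tested in both tissues, 90 were higher in both mutants of brain and of ovary, where 9.79 were expected for independent lists (Fisher's exact test, two-sided, odds ratio 27.8, adjusted p = 1.3e-69). All 8 genes called in S2 cells at 48 h were higher in both ovary mutants (0.433 expected, Fisher's exact test adjusted p = 1.0e-10), and 7 of them in both brain mutants (0.0829 expected, 2.3e-13). At 24 h, 7 of 7 were shared with ovary (0.379 expected, Fisher's exact test adjusted p = 1.5e-09) and 6 with brain (0.0726 expected, 1.4e-11). The 7 genes higher in all 3 systems were snu, rtv, qsm, Rcd6, CG9782, Cad96Ca and Dlish, and conv missed only brain mutant 1 (1.18 ± 0.26, edgeR adjusted p = 0.0567). lft, a Fat pathway gene, rose from 1.5 to 65.2 and 65.5 CPM in brain and from 0.611 to 83.5 and 87.4 in ovary. The protocadherin gene ds rose from 4.21 to 45.9 and 41.3 CPM in brain and from 10.4 to 233 and 250 in ovary, and f, an actin bundler of bristles, from 0.241 to 16.6 and 19.0 and from 4.58 to 56.6 and 55.5. Lower in both mutants of both tissues were 5 genes (2.04 expected, Fisher's exact test adjusted p = 0.0496, and 0.0827 in the family with blocked S2 calls): LanB2 and, named after their values were seen, egr, Nepl4, Orct and wdp. With blocked S2 calls a smaller part was shared: of genes higher at 48 h, 26 of 105 with brain (1.09 expected, Fisher's exact test adjusted p = 1.2e-29) and 30 of 91 with ovary (4.92 expected, 3.0e-16), and at 24 h 22 of 70 and 26 of 61. Of genes lower at 48 h with the block, 1 of 77 was shared with brain (0.308 expected, Fisher's exact test adjusted p = 0.296) and 2 of 70 with ovary (4.49 expected, 0.324), and at 24 h 1 of 56 and 1 of 53.

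**Figure D2:**
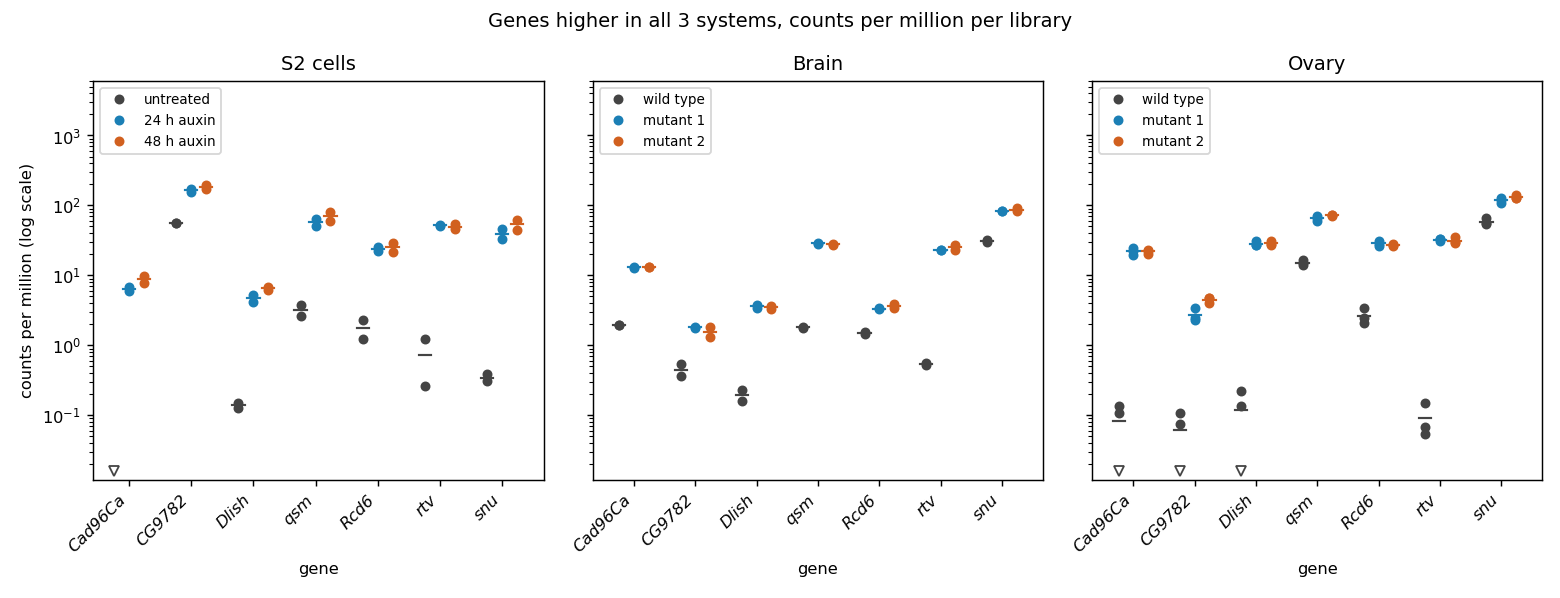
CPM (log axis) of the 7 genes higher in S2 cells, brain and ovary, by group in 3 panels. Points are libraries, short lines are group means, and open triangles at the lower edge are libraries with 0 counts, such as untreated S2 cells for Cad96Ca.

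The mutant effect was compared between tissues by its difference, brain minus ovary. It differed in 631 of 10029 genes, 263 with a more positive change in brain and 368 with a more positive change in ovary. This split followed the scaling: 41.7% were more positive in brain with TMM, 57.0% with RLE size factors (413 and 312) and 61.5% with DESeq2 (615 and 385). kkv was not called in brain (0.83 ± 0.45 and 1.16 ± 0.44 in mutants 1 and 2, edgeR adjusted p = 0.69 and 0.34), and its difference was -8.53 ± 0.74 (1.5e-05). uif rose more in ovary (-7.20 ± 0.19, edgeR adjusted p = 7.9e-12), as did Tep3 (-3.48 ± 0.15, 1.7e-09), and the change of CBP was more positive in brain (3.20 ± 0.14, 2.2e-09). lov, a BTB-domain gene, had a mean change of -3.42 in ovary and 0.13 in brain (difference 3.54 ± 0.13, edgeR adjusted p = 4.3e-10). snu did not differ past the threshold (0.35 ± 0.11, edgeR adjusted p = 0.0737). Without brain wild-type library 1 the call of CG11247 (0.34 ± 0.08) was lost (edgeR adjusted p = 0.11). Without that library the count was 373, and without brain wild-type library 2 it was 303.

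**Figure D3:**
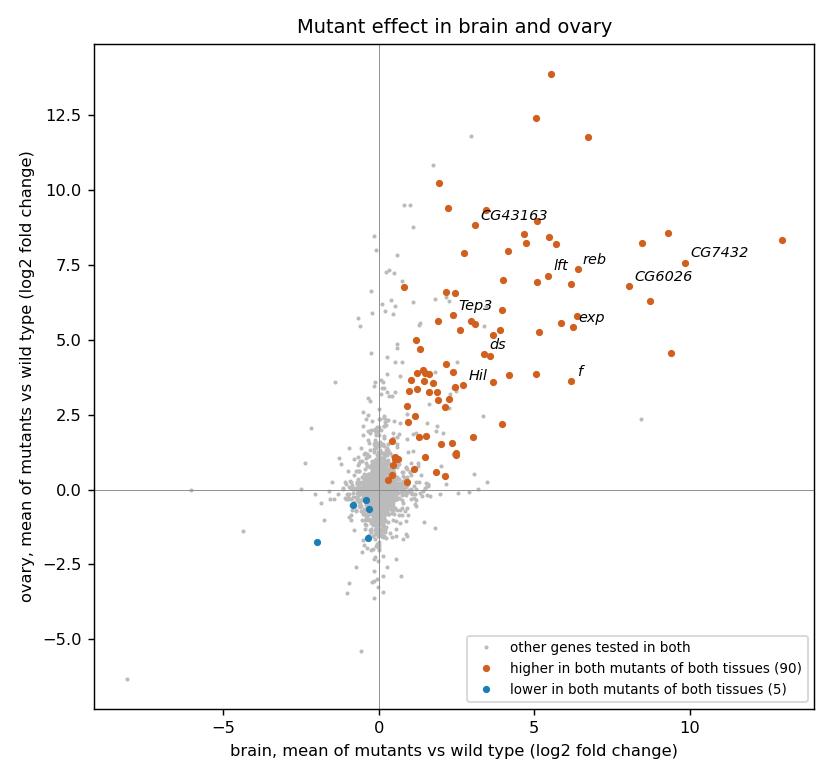
Mean log2 fold change of both mutants against wild type in brain (horizontal axis) and ovary (vertical axis) for genes tested in both. Orange points are the 90 genes higher in both mutants of both tissues, blue points the 5 lower, and 10 genes are labelled.

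Because the gene and the balancer lie on chromosome 3, the share of called genes there was compared with that of other tested genes. In brain 46.6% of genes called in both mutants lay on chromosome 3 against 43.8% of the others (Fisher's exact test, two-sided, odds ratio 1.12, 95% interval 0.849 to 1.47, adjusted p = 0.864). In ovary it was 43.4% against 43.5% (odds ratio 0.994, 0.874 to 1.13, Fisher's exact test adjusted p = 0.949). Of 241 tested ovary genes within 2 Mb of CG11247, 57 were called in mutant 1 and 43 in mutant 2. Over all 8312 tested ovary genes 1953 and 1340 were called, which is a similar share.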

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

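The tests of chromosome 3, of S2 cells, of auxin, of depth, of small changes, of calls without 3 ovary libraries, of hemocytes and of fat body and the counts of other splits were chosen after the result was seen, and the test of the shift of 3 ovary libraries over all called genes by Pearson correlation before.

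The 90 genes higher in both mutants of brain and of ovary recur across tissues, and the mutation is the biological explanation that the design gives. Background linked to chromosome 3 that acts only on genes of that chromosome would place nearly all of them there. Of the set 51.1% lay on it (95% interval 40.3 to 61.8), against 43.4% of other tested genes, which argues against that form. Linked background that acts on genes of other chromosomes too stays open, as the share cannot test it. S2 cells were not dissected and flies had no auxin, and 21 genes of the set were called higher in S2 cells at 48 h with the replicate block (18 at 24 h), against at most 5 (and 4) in 10000 random lists matched on untreated expression, which argues against tissue carried over at dissection and against auxin for these 21, for which a response to loss of the protein may be the explanation, as a hypothesis. Among S2 genes also tested in both tissues, 87.5% of the 8 called at 48 h without the block were in the set. With the block it was 13.1% of 160, and 23.1% of the 91 higher ones, as only higher genes can be in the set. Auxin therefore stays open for S2 calls outside the set. For the other 69 genes of the set carried-over tissue and the mutation cannot be told apart, as no library holds such tissue alone. Values over the whole set, with the 21 included, do not settle it. In both untreated libraries 16 genes reached or passed the low-count limit of 1.31 CPM (11 higher at each time). Their median log2 change was 0.24 at 48 h (highest of 10000 random lists 0.228) and 0.14 at 24 h (49 random lists as high). The need to pass at both times was set after the 48 h value was seen. Without a filter, 78 genes (55 higher) had 0.68 at 48 h and 0.66 at 24 h (highest random 0.371 and 0.268), a fitted median that rests on genes near 0.

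The 1143 genes called in both ovary mutants were weighed against depth and the shift of 3 libraries. Libraries thinned to 14.1 M counts gave 1096 calls, 1026 of them shared, which argues against depth. Across all 1143 genes the shift correlated with the mutant effect at -0.011 (Pearson, interval -0.0689 to 0.0470 as if genes were independent; Spearman -0.203), and without the 3 libraries 497 of the genes were called again, which argues against the shift as the cause of the whole. Each group holds 1 of the 3 libraries. Group means on the second component were 0.701 (wild type), -0.105 and -0.596 (mutants 1 and 2). The first component separated wild type from mutants, and components are uncorrelated by construction. These means were thus largely fixed in advance and say nothing on balance between groups. The shift stays open for 578 genes not called again among the 804 that changed by less than 2-fold, where the correlation was -0.489 (Pearson), and the mutation remains untested as their cause.

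Hemocyte markers were lower in mutant brains. Camera called the list at the preset correlation but not with an estimated one (camera adjusted p = 0.803), and fry did not call it (adjusted p = 0.0712). Fewer hemocytes in the samples may be the cause. All 5 plasmatocyte markers were called lower (Sr-CI -0.69, NimC2 -1.10, Hml -0.62, eater -0.98, NimC1 -0.63). The falls were unequal (Cochran Q 23.3, where errors alone give 4 on average), which leaves this open, as other brain cells can hold some of these transcripts. Less fat body on the samples also stays open: 7 abundant fat body transcripts had a mean change of -0.249 (interval -0.654 to 0.157), with Obp44a lower and Tsf1 at 0.59. Not among the 7 were the called markers Desat1 (0.34, 448 CPM in wild type), Fbp1 (-2.22, 2.76 CPM) and Lsp1gamma (-2.39, 2.10 CPM). A change of gene activity in hemocytes was not tested.

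In ovary, other splits of the libraries were counted. Mutant 1 against wild type (1953 calls) and mutant 2 against wild type (1340) were each matched by 1 of 10 splits, the real one, with 0 calls in the highest other, and 10 splits are too few for a share under 0.05. For mutant 2 against mutant 1 (1 call, highest other 1), 2 of 10 splits gave as many, again too few. For the mean of both mutants 2 of 100 splits gave as many as 2379 (highest other 2459), and for genes called in both 2 of 100 gave as many as 1143 (highest other 1212). At that share this argues against a chance division of the libraries. It cannot test any other difference that all wild-type libraries share. The higher split kept the wild-type libraries together, and the 98 that broke them up reached at most 249 and 1. Groups of mixed genotype hold the genotype difference in their spread, which can lower their calls.

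The change in the mutants differed between brain and ovary in 631 genes by the test of the difference. Among named genes the log2 difference, brain minus ovary, was 7.66 for CG12607, 3.99 for brp, 3.98 for naz, 3.54 for lov, 3.44 for bnb, 3.20 for CBP, 2.88 for CG9380, 2.54 for f, 2.01 for RhoGAP100F, 1.76 for tty, 1.74 for qsm, 1.72 for Mco1, 1.58 for CG8745, 1.52 for CG10175 and 0.34 for CG11247. It was -0.74 for GstD3, -0.78 for Hil, -1.18 for ds, -1.22 for Tep1, -1.72 for lft, -1.79 for Obsc, -2.14 for eater, -2.16 for Rcd6, -2.98 for rtv, -3.48 for Tep3, -3.76 for CG9782, -3.85 for Dlish, -3.95 for Sb and -4.26 for conv. It was -5.20 for Cad96Ca, -5.76 for CG43163, -5.99 for CG6118, -7.20 for uif, -7.68 for dyl, -8.53 for kkv, -8.61 for CG11905, -8.65 for spz4 and -9.40 for slf. Fitted differences of genes near 0 in a tissue depend on the prior count. The low-count filter left CG12607, brp, naz and eater out of the fit of ovary alone. In brain brp and naz hardly changed (mean log2 change -0.0079 and 0.0042), so their differences come from low ovary counts. CG12607 rose in brain (9.39) and eater fell (-0.98). The call of naz (edgeR adjusted p = 0.0349) was lost without brain wild-type library 2 (0.0572), ovary wild-type library 1 (0.0569) or 2 (0.157), ovary mutant 1 library 2 (0.0541) or 3 (0.056), or ovary mutant 2 library 1 (0.0503), 2 (0.0576) or 3 (0.0505), and without the 3 libraries that stand apart (0.188).

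Of the genes named by the rule fixed beforehand, mutant 2 differed from mutant 1 in CG11247 in brain (0.69) and ovary (1.27) and in CBP in brain (-0.94), with both brain calls lost without mutant 1 library 1 (edgeR adjusted p = 0.108 and 0.131) and that of CBP without mutant 1 library 2 (0.105).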

How the results depend on the processing

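Summed isoforms, ovary fits without the 3 libraries that stand apart, and blocked S2 calls in the overlaps were chosen after the data were seen. Apart from the S2 counts with the replicate block, the cause of each change below was not tested. DESeq2 called 15 genes at S2 24 h, 18 at 48 h, 15 for brain mutant 2 against mutant 1, 11 for the same in ovary and 1000 for brain minus ovary. Without a low-count filter there were 26, 36 and, for ovary mutant 2 against mutant 1, 2. The replicate block gave 138 and 191 in S2 cells and 7 for brain mutant 2 against mutant 1, and moved no other count of genes by over 1.5 times. Same-numbered libraries correlated at 0.19, 0.06 and 0.05 in brain and from -0.34 to 0.27 in ovary. In brain the second principal component (15.1% of the variance) separated the numbers in each group, so a weak pairing stays open there. Not every ovary library correlated best with its own number. Without the 3 ovary libraries that stand apart there were 614 for mutant 2, 18 for mutant 2 against mutant 1 and 527 in both. An estimated correlation left 0 gene lists called at S2 24 h, 0 at 48 h, 0 in brain and 0 in ovary, and fry 0, 0 and 0 in all but ovary. The block gave 5 and 4 lists in S2 cells, and fat body markers in ovary (camera adjusted p = 0.011). The overlap of 5 lower genes had an adjusted p of 0.0827 in the family with blocked S2 calls. RLE factors moved no total by over 1.5 times, but for brain minus ovary they moved the genes with a more positive change in brain from 263 to 413.

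With single libraries left out, counts ranged from 1 to 4 (S2 24 h), 4 to 9 (S2 48 h), 149 to 203 (brain mutant 1), 167 to 539 (brain mutant 2), 0 to 80 (brain mutant 2 against mutant 1), 201 to 536 (brain mean) and 142 to 270 (brain, both). In ovary they ranged from 996 to 2225 (mutant 1), 604 to 1207 (mutant 2), 1 to 6 (mutant 2 against mutant 1), 1140 to 2673 (mean) and 527 to 1260 (both), and for brain minus ovary from 303 to 793. Lists called ranged from 1 to 5 (S2 24 h), 2 to 4 (S2 48 h), 6 to 9 (brain) and 8 to 9 (ovary). A group left with 1 library was assumed to vary like the others, and these fits had no replicate block. Turned in direction were ribosomal protein genes at S2 24 h without untreated library 1 (camera adjusted p = 0.813, range 4.2e-05 to 0.994 over single libraries left out) and heat shock genes without untreated library 2 (0.0141 at 24 h, 0.00836 at 48 h) or 24 h library 1 (0.00911), with ranges of 1.2e-04 to 0.0141 at 24 h and 3.1e-04 to 0.158 at 48 h. Of 140 values of named genes, 134 kept their side of the threshold with DESeq2, 139 with RLE, 134 without a filter and 134 with the block, and none turned in direction. Depth was lowest in S2 cells. At the same depth, the replicate block gave 75 higher and 63 lower genes at 24 h, against 7 called without it. At 48 h it gave 110 and 81, against 8. Spread between libraries tied to the replicate number was thus part of the low counts of calls there, and the part of depth was not tested.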

Other observations

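The 4 gene lists below, tested in brain and ovary as 1 family of 8 tests, were chosen after the data were seen. Genes of the cuticle and of its patterning were among those higher in both mutants. Zona pellucida domain genes, which shape apical matrices, had 4 of 6 higher in brain (0.104 expected, Fisher's exact test, two-sided, adjusted p = 3.5e-06) and 6 of 8 in ovary (0.592 expected, 6.3e-06), such as nyo (6.26 and 6.08 in brain mutants 1 and 2), dpy (3.49 and 3.65) and, in ovary, neo (4.69 and 4.78). Chitin synthesis and processing genes had 6 of 23 higher in brain (Fisher's exact test adjusted p = 4.0e-06) and 12 of 20 higher and 1 lower in ovary (1.4e-08), with knk (4.39 and 4.46), serp (2.26 and 2.45) and verm (2.23 and 2.67). Cuticle protein genes had 4 of 21 higher in brain (4.2e-04) and 5 of 8 in ovary (Fisher's exact test adjusted p = 1.2e-04), with Cpr56F at 11.3 in both brain mutants. Fat-Dachsous pathway genes, which set planar polarity and growth, had 4 of 9 higher in brain (Fisher's exact test adjusted p = 1.4e-05) and 7 of 9 in ovary (1.5e-06), with fj (5.81 and 5.93), ft (3.00 and 3.22) and Fbxl7 (6.59 and 6.62) in ovary. These lists were drawn up from genes already seen to rise, so the p values are not independent evidence.

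Sb was higher in both mutants of both tissues, from 0.0807 CPM to 2.45 and 3.23 in brain (edgeR adjusted p = 3.4e-05 and 1.8e-05) and from 0.0459 to 25.2 and 24.3 in ovary. Whether a balancer allele was present in the dissected females is not given in the sources used here.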
